A study of Mus musculus with 12 samples.

How the data were processed

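Gene expression was measured on 12 one-colour Affymetrix arrays of mouse bone marrow macrophages, each hybridised with RNA from 1 culture. Cells came from wild-type (WT) mice or from mice with a kinase-dead form of IRAK4 (KD). Each strain had 3 conditions, and each of the 6 groups had 2 biological replicates, per the labels. The conditions were 4 h without LPS, 1 h with LPS at 1 µg/ml and 4 h with LPS at 1 µg/ml. The unstimulated cultures were kept for 4 h, so at 1 h the effect of LPS and the time in culture differ together. The labels do not say whether the replicates came from separate animals, and p-values therefore measure the spread between the arrays of a group.

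Per the labels' protocols, cells were grown in medium with fetal calf serum and L-929 conditioned medium, total RNA was extracted with RNeasy kits and labelled with the NuGEN Ovation protocol. The deposited values are linear signal intensities per probe set, 1 column per array, made with MAS5 per the submitters' processing notes. The MAS5 version, the scanner settings and any filter are not given in the sources used here. On every array the mean signal after trimming 2% from each end was 150, which is the target to which the authors' values had been scaled as far as the values show it. They were therefore used as deposited, without further rescaling. Array medians lay between 18.9 and 26.9, and between 17.06% and 22.91% of the values of an array were under the pseudocount. Arrays carry no read depth, and their number limits the precision.

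Of 45101 probe sets, 64 were array controls and were not tested. The annotation table gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and no gene was named from a probe set with several symbols. The Entrez identifiers of 34754 of the 1-symbol probe sets were found in the gene table of assembly GRCm38.p6 and those of 204 were not, and 0 symbols changed in that update. The gene table was used only for names and for which genes neighbour each other. A total of 0 probe sets carried the symbol Irak4, alone or among several, and the transcript of the targeted gene was not analysed here. A change that inactivates a kinase need not alter its transcript, so the strain labels were not checked by that gene.

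Signals were turned into log2(value + 4.4), where 4.4 is the 20th percentile of all values. Fold changes are on this scale, which understates the change of genes with low signal. A probe set was tested if its signal was above the array median on at least 2 of the 12 arrays, which left 27931 probe sets, 23324 of them with 1 symbol, for 12914 genes. A linear model with 1 mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance prior that follows mean signal. Adjusted p-values are limma's with Benjamini-Hochberg adjustment within each comparison, and a probe set was called at an adjusted p under 0.05. The 11 comparisons were LPS at 1 h and at 4 h against no LPS and LPS at 4 h against 1 h in each strain, KD against WT in each condition, and the differences between the strains' responses at 1 h and at 4 h (interactions, KD response minus WT response). A gene was represented by its tested probe set with the highest mean, preferring identifiers without the suffix for cross-hybridising sets. Errors are standard errors (SE) of the fit unless given as standard deviations (SD).

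A total of 22 gene lists were used: immediate early genes and MAP kinase phosphatases, NF-κB components and feedback genes, inflammatory and regulatory cytokines, chemokines, interferon-induced genes, inflammatory enzymes and effectors, Toll-like receptor pathway components, regulators of cytokine mRNA decay, antigen presentation and co-stimulation, cell cycle, macrophage identity, sterol synthesis and lipid handling, glycolysis and hypoxia response, the unfolded protein response, ribosomal proteins, and markers of T and NK cells, B cells, neutrophils and their precursors, dendritic cells, stromal cells, erythroid cells, and mast cells and basophils. Each list was tested in each comparison with camera (limma) at a preset correlation of 0.01, with adjustment over all 242 tests, and again with an estimated correlation. The named genes were, per comparison, the 10 with the highest and the 10 with the lowest log2 change among called genes whose replicates did not overlap, and up to 4 called members of each list with the largest change. Where a list had no called member, its member with the highest mean signal was named. Fewer were printed where space was short, in rank order or, where many calls depended on 1 array, those called in every fit with 1 array left out. The groups, the tests, the lists, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

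Alternatives were quantile normalization, no filter, a stricter filter at the 75th percentile, pseudocounts of 1 and of 23.4 (the median), a variance prior without a trend, fits on the arrays of the comparison alone, the replicate number as a block, a minimum absolute log2 change of 1, and each of the 12 arrays left out in turn. For the gene lists, an estimated correlation and every tested probe set in place of 1 per gene were tried as well. A further alternative, chosen after the data were seen, replaced the interaction by KD against WT under LPS. A fit without 1 array leaves a group with 1 array, which is then assumed to vary like the other groups.

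The fit was tested on data simulated with the group means and moderated spreads of the 27931 probe sets, where the tested difference was set to 0 except for 200 changed probe sets in each of 5 runs. For WT at 4 h against no LPS, 12.2% of log2 changes of 0.5, 44.5% of changes of 1 and 72.1% of changes of 2 were recovered, and 6.35% of the calls were false. For the interaction at 4 h these shares were 2.99%, 24.8% and 58.5%, with 6.84% of the calls false. With camera, a shift of -0.5 given to the cytokine list among 12914 genes was found in 5 of 5 runs, and 0 of 105 tests of unchanged lists were called. The simulated noise was independent between genes, so these runs do not test camera for lists whose genes vary together. The simulated spreads came from the fit with a trend in the variance prior, so that prior was not tested either. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.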

Results

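The data comprised 12 arrays of bone marrow macrophages from WT mice and from mice with kinase-dead IRAK4, the serine/threonine kinase that joins MyD88 below Toll-like receptors and the interleukin-1 receptor. LPS, a component of the outer membrane of Gram-negative bacteria, is sensed by Toll-like receptor 4. The 6 groups of 2 arrays covered each strain without LPS, after 1 h and after 4 h of LPS. Between replicates, Spearman's correlation of signals across probe sets was 0.932 to 0.959. Array medians were 18.9 to 22 in WT and 24.2 to 26.9 in KD, at the same trimmed mean of 150. The log2 ratio of 3' to 5' control probe sets was highest on KD unstimulated replicate 1 (1.35 for Gapdh and 3.04 for Actb). The other 11 arrays lay between 0.81 and 1.17 for Gapdh and between 2.22 and 2.85 for Actb.

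After 1 h of LPS, WT macrophages raised cytokine, chemokine and immediate early genes. Il1b, which encodes interleukin-1β, went from a signal of 9.40 ± 1.98 to 779 ± 111 (SD, n = 2), a log2 change of 5.83 ± 0.18 (SE). Cxcl1, a chemokine that attracts neutrophils, rose by 5.49 ± 0.14, Socs3, an inhibitor of cytokine receptor signalling, by 4.81 ± 0.34 and Tnf, which encodes tumour necrosis factor, by 4.63 ± 0.14. Tnfsf9 (4.50 ± 0.24), Cxcl5 (4.26 ± 0.21), Csrnp1 (4.08 ± 0.20), Tnfaip3 (4.06 ± 0.16), Il1a (3.93 ± 0.44) and Il10 (3.86 ± 0.51) completed the 10 largest increases, with limma adjusted p of at most 5.98e-05. Tnfrsf11b, the decoy receptor osteoprotegerin, fell by 2.84 ± 0.26 (adjusted p = 6.02e-07) and Zfp950 by 2.47 ± 0.32.

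By list, 18 of the 21 immediate early genes and MAP kinase phosphatases rose in WT at 1 h and 0 fell (19 rose adjusted over the list alone), with a median log2 change of 2.02 and a camera adjusted p of 2.64e-37. Among them were Dusp5, a phosphatase of ERK (3.82 ± 0.15), Fosb (3.65 ± 0.63) and Egr1, a zinc finger transcription factor (3.51 ± 0.16). Of 18 NF-κB components and feedback genes, 14 rose (17 adjusted over the list alone; median 1.14), including Nfkbiz (2.83 ± 0.11) and Nfkbie (2.14 ± 0.11). Of 19 cytokines, 8 rose (10 adjusted over the list alone; median 1.01), and of 20 chemokines, 10 rose (11 adjusted over the list alone; median 0.776), among them Cxcl2 (3.68 ± 0.13). Interferon-induced genes had 18 of 37 higher and 1 lower (22 and 1 adjusted over the list alone), a median of 0.472 and Irf1 (2.31 ± 0.17) and Ifit1 (1.47 ± 0.14) in the lead. Inflammatory enzymes and effectors had 9 of 21 higher (10 adjusted over the list alone; median 0.497), led by Acod1, the itaconate-producing enzyme (2.17 ± 0.09). The glycolysis and hypoxia response list had 5 of 18 higher and 1 lower (6 and 1 adjusted over the list alone), with Slc16a3, a lactate transporter gene, up by 1.23 ± 0.25 (call lost in 2 of the 12 fits that left out 1 array and without a trend in the variance prior) and Vegfa by 1.06 ± 0.18, and a camera adjusted p of 0.000242 (adjusted p = 0.0257 with an estimated correlation). Regulators of cytokine mRNA decay had 4 of 17 higher and 1 lower (5 and 1 adjusted over the list alone), among them Zfp36 (3.20 ± 0.12), which encodes tristetraprolin. That list's median was -0.0145 and its mean 0.345, and its camera adjusted p of 0.022, for an increase, became an adjusted p = 0.369 with an estimated correlation. Toll-like receptor pathway components had 5 of 26 higher and 1 lower (7 and 1 adjusted over the list alone). The camera adjusted p was 0.0219, and the adjusted p = 0.0898 with an estimated correlation. Antigen presentation and co-stimulation had 5 of 18 higher (8 adjusted over the list alone, where 1 fell). Camera gave an adjusted p of 3.76e-05, and the adjusted p = 0.0793 with an estimated correlation. Mki67, a proliferation marker, rose by 2.08 ± 0.24. The cell cycle list had 2 of 27 higher (4 adjusted over the list alone). As a list, the camera adjusted p was 0.00453, and the adjusted p = 0.207 with an estimated correlation.

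In all, 1709 probe sets were called in WT at 1 h, 806 higher and 903 lower. A change of at least 2-fold was reached by 301 of the higher and 247 of the lower. Higher calls exceeded lower ones without 3 of the arrays, without a trend in the variance prior and among changes of at least 2-fold, and lower calls exceeded higher ones in the other fits. The count was 739 without WT unstimulated replicate 1 (425 higher, 314 lower), 929 without WT unstimulated replicate 2 (555 and 374) and 829 without WT LPS 1 h replicate 2 (465 and 364). It was 487 with a variance prior without a trend (290 and 197). Of 60 called genes that the naming rule gave, 37 were called in every fit with 1 array left out. Here and in the other comparisons, each gene of the naming rule given as called was called in all 12 such fits except where a number of lost calls is given. Genes outside that rule, given further below as called in opposite directions in the strains, were not checked in this way.

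At 4 h of LPS, 5 of the 10 largest WT increases were cytokine or chemokine genes, and more probe sets were called than at 1 h. Il6, which encodes interleukin-6, rose from a signal of 0.75 ± 0.212, under the pseudocount, to 1751 ± 40.4 (SD, n = 2). Il1b reached 2744 ± 278, a log2 change of 7.64 ± 0.18 (SE), and Il1a rose by 6.65 ± 0.44. Nlrp3, the inflammasome sensor, rose by 5.78 ± 0.20, followed by Cxcl1 (5.74 ± 0.14), Cxcl5 (5.73 ± 0.21), Shisa3 (5.45 ± 0.71), the orphan nuclear receptor gene Nr4a3 (5.24 ± 0.40), Olr1 (5.22 ± 0.34) and Rasgrp1 (5.17 ± 0.65). Cnr2, a cannabinoid receptor gene, fell by 3.55 ± 0.48, Rab39 by 3.25 ± 0.27, Lpar6 by 3.06 ± 0.13 and Fos by 3.01 ± 0.12, all with limma adjusted p of at most 2.29e-05.

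All 18 measured NF-κB components and feedback genes rose in WT at 4 h (18 adjusted over the list alone; median log2 change 2.59, camera adjusted p = 4.56e-33), including Traf1 (3.88 ± 0.22), Tnfaip3 (3.71 ± 0.16), Nfkb2 (3.22 ± 0.25) and Icam1, an adhesion molecule (3.14 ± 0.11). Of 20 chemokines, 19 rose (19 adjusted over the list alone, where 1 fell; median 2.92), among them Cxcl10 (5.07 ± 0.20). Of 19 cytokines, 13 rose (14 adjusted over the list alone; median 2.41), with Tnf at 5.13 ± 0.14. Interferon-induced genes had 29 of 37 higher and 1 lower (31 and 1 adjusted over the list alone; median 1.26), with the antiviral genes Mx1 (4.85 ± 0.22) and Ifit1 (4.47 ± 0.14). Inflammatory enzymes and effectors had 17 of 21 higher (17 adjusted over the list alone; median 1.73), including Ptges, prostaglandin E synthase (4.13 ± 0.16), and Serpinb2 (4.00 ± 0.29). Toll-like receptor pathway components had 14 of 26 higher and 2 lower (15 and 2 adjusted over the list alone; median 0.494), led by Tlr2 (3.38 ± 0.13) and Peli1, a ubiquitin ligase (2.63 ± 0.12). In the antigen presentation and co-stimulation list, 9 of 18 rose (9 adjusted over the list alone, where 1 fell), with Cd40 up by 4.88 ± 0.16. Its camera adjusted p was 5.86e-06, and the adjusted p = 0.0619 with an estimated correlation. Immediate early genes were 7 higher and 2 lower of 21 (9 and 2 adjusted over the list alone). Its camera adjusted p was 0.00175, and the adjusted p = 0.0947 with an estimated correlation. Regulators of cytokine mRNA decay were 6 higher and 3 lower of 17 (9 and 4 adjusted over the list alone). The camera adjusted p was 0.00954, and the adjusted p = 0.326 with an estimated correlation.

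Other groups moved as single genes in WT at 4 h. Mki67 rose by 2.71 ± 0.24, Dhcr7, an enzyme of cholesterol synthesis, fell by 2.14 ± 0.12, the cyclin gene Ccnd1 by 1.88 ± 0.10 and Mertk, a receptor for apoptotic cells, by 1.19 ± 0.24, whereas Herpud1, an endoplasmic reticulum stress gene, rose by 1.56 ± 0.15. As lists, sterol synthesis and lipid handling (1 higher and 5 lower of 21; 1 and 6 adjusted over the list alone), the cell cycle (1 and 6 of 27; 1 and 6), macrophage identity (1 and 4 of 18; 1 and 4), glycolysis and hypoxia (4 and 1 of 18; 4 and 3) and the unfolded protein response (4 and 4 of 15; 4 and 4) had camera adjusted p of 0.314, 0.261, 0.831, 0.209 and 0.64. Ribosomal proteins (0 higher and 1 lower of 16; 0 and 1) had a camera adjusted p of 0.169. Markers of other cell types gave camera adjusted p of 0.672 for T and NK cells (1 of 4 lower), 0.82 for B cells (0 of 6 called), 0.952 for neutrophils and their precursors (0 of 6), 0.545 for dendritic cells (0 of 4), 0.592 for erythroid cells (0 of 5) and 0.762 for mast cells and basophils (0 of 4). Stromal cell markers had 2 of 12 lower (3 adjusted over the list alone), a median of -0.0371 and a camera adjusted p of 0.589.

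A total of 4782 probe sets were called in WT at 4 h, 1940 higher and 2842 lower, with 875 and 1029 of them changed at least 2-fold. The median log2 change of all tested probe sets was -0.119, and -0.0532 after quantile normalization. The count was 2942 without WT unstimulated replicate 1, 2899 without WT LPS 4 h replicate 1 and 3150 without a trend in the variance prior.

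**Figure D1:**
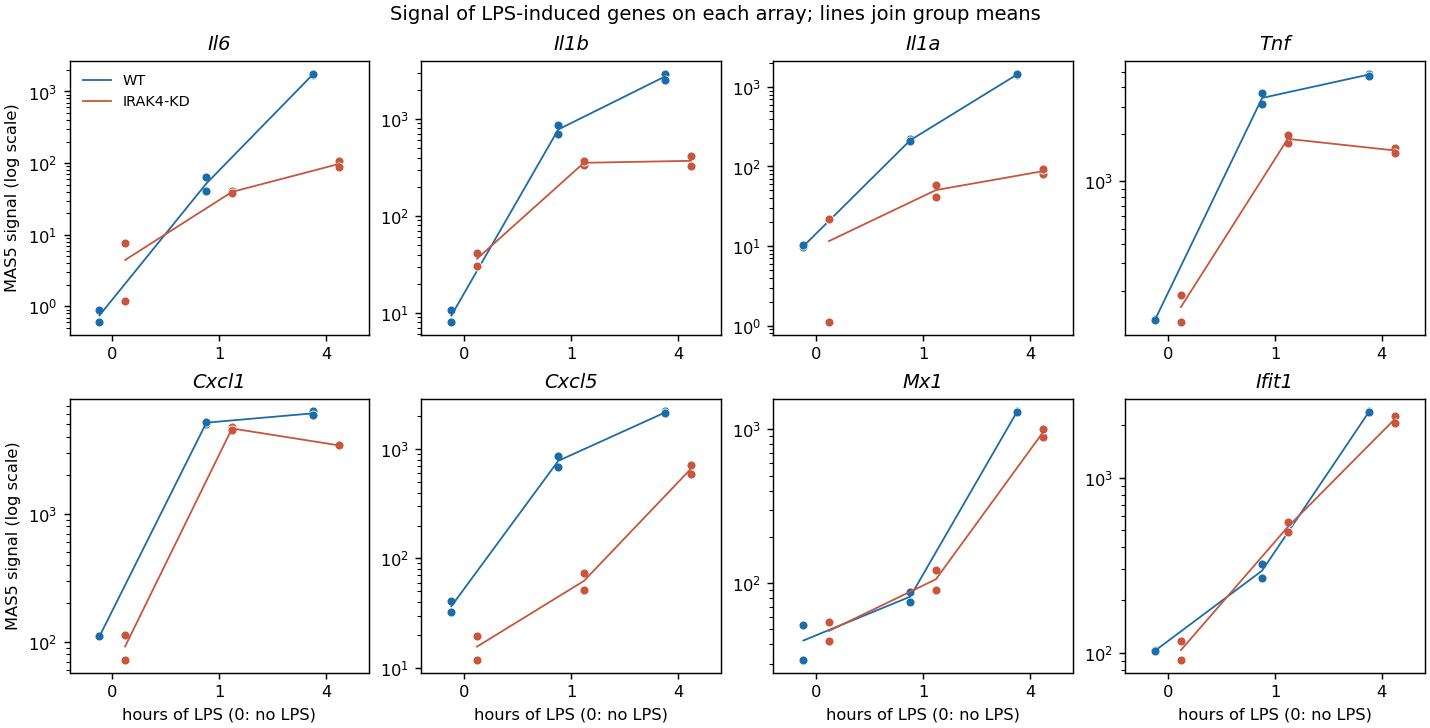
MAS5 signal (log axis) of 8 LPS-induced genes on each of the 12 arrays against hours of LPS, with lines joining the means of 2 arrays per strain and condition. At 4 h, mean Il6 signal was 1751 in WT and 97.3 in KD, while Ifit1 was at 2375 in WT and 2153 in KD.

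Between 1 h and 4 h of LPS, immediate early genes of WT macrophages declined while interferon-induced genes went on rising. Fos fell by 4.47 ± 0.12, Dusp5 by 3.60 ± 0.15, Fosb by 3.31 ± 0.63 and Egr1 by 3.06 ± 0.16, and 13 of 21 immediate early genes fell (16 adjusted over the list alone; median -1.33, camera adjusted p = 6.9e-13). The largest increases were Itgb8, an integrin chain (5.33 ± 0.47), Shisa3 (5.22 ± 0.71), Il6 (4.99 ± 0.35), Rasgrp1 (4.97 ± 0.65), Adamts4 (4.62 ± 0.24) and Cd40 (4.12 ± 0.16). Interferon-induced genes had 24 of 37 higher and 3 lower (25 and 3 adjusted over the list alone; median 0.962), led by Mx1 (3.93 ± 0.22) and Cmpk2 (3.85 ± 0.20), and 14 of 20 chemokines rose and 1 fell (16 and 1 adjusted over the list alone). Of the cell cycle genes, 12 of 27 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.749). Camera gave an adjusted p of 0.00101, and the adjusted p = 0.148 with an estimated correlation. This comparison called 4423 probe sets, 1982 higher and 2441 lower, and 2740 without WT LPS 4 h replicate 1, 2944 without WT LPS 4 h replicate 2 and 2732 without a trend in the variance prior.

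In KD macrophages, 1 h of LPS raised many of the same kinds of genes. Cxcl1 rose by 5.62 ± 0.14, Nr4a3 by 4.12 ± 0.40, Tnfsf9 by 4.00 ± 0.24, Fosb by 3.99 ± 0.63, Dusp5 by 3.74 ± 0.15 and Pde4b, a cyclic AMP phosphodiesterase, by 3.64 ± 0.11. Tnf went from 158 ± 44.9 to 1867 ± 169 (SD, n = 2), a log2 change of 3.55 ± 0.14, and Il1b rose by 3.15 ± 0.18 (adjusted p = 9.55e-10). Immediate early genes had 12 of 21 higher and 1 lower (14 and 1 adjusted over the list alone; median 1.11), NF-κB genes 15 of 18 higher (16; median 1.14), cytokines 7 of 19 (9; median 0.745), chemokines 9 of 20 (13; median 1.01), and interferon-induced genes 24 of 37 with 1 lower (26 and 1; median 0.66), with camera adjusted p of at most 1.76e-11. Inflammatory enzymes and effectors had 11 higher and 1 lower of 21 (13 and 1 adjusted over the list alone; median 0.519). Stromal cell markers moved with these groups: 5 of 12 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.56), among them Col6a1 (1.35 ± 0.16) and Thbs2 (1.17 ± 0.18). The stromal list's camera adjusted p was 0.000822, and the adjusted p = 0.227 with an estimated correlation. The comparison called 1527 probe sets, 886 higher and 641 lower. The count was 1009 without KD unstimulated replicate 2, 818 without KD LPS 1 h replicate 1, 905 without KD LPS 1 h replicate 2, 506 without a trend in the variance prior and 805 on the 4 arrays of the comparison alone.

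At 4 h, 6 of the 8 largest single increases in KD were chemokine or interferon-induced genes, whereas by list the median was higher for chemokines, NF-κB genes and inflammatory enzymes and effectors than for interferon-induced genes. Cxcl1 rose by 5.19 ± 0.14, Cxcl5 by 5.07 ± 0.21, Cxcl10 by 4.72 ± 0.20, the protease gene Adamts4 by 4.42 ± 0.24, Ifit1 by 4.33 ± 0.14, Cd69 by 4.27 ± 0.15, Cxcl3 by 4.27 ± 0.16 and Mx1 by 4.18 ± 0.22. Il6 reached 97.3 ± 12.3 (SD, n = 2), from 4.45 ± 4.60, a log2 change of 3.62 ± 0.35, and Il1b rose by 3.21 ± 0.18. The unstimulated Il6 signals, 7.7 and 1.2, lay around the pseudocount, so the size of the Il6 change depends on that constant. NF-κB genes had 17 of 18 higher (17 adjusted over the list alone; median 1.93), chemokines 14 of 20 (14; median 2.39), interferon-induced genes 26 of 37 with 1 lower (27 and 1; median 1.12), inflammatory enzymes and effectors 17 of 21 (19; median 1.37) and cytokines 10 of 19 (11; median 0.746), each with a camera adjusted p of at most 1.2e-10. Immediate early genes had 3 of 21 higher and 4 lower (5 and 4 adjusted over the list alone), and their camera adjusted p was 0.475. Toll-like receptor pathway components had 7 of 26 higher and 2 lower (9 and 2 adjusted over the list alone; median 0.217), led by Tlr2 (3.12 ± 0.13). Stromal cell markers had 7 of 12 higher (9 adjusted over the list alone; median 0.668), led by Col6a1 (1.54 ± 0.16) and Pdgfrb (0.95 ± 0.21, call lost in 2 of the 12 fits). As a list, the camera adjusted p was 4.16e-08, and the adjusted p = 0.0664 with an estimated correlation. Ribosomal proteins had 5 of 16 lower (8 adjusted over the list alone; median -0.223). Its camera adjusted p was 0.00839, and the adjusted p = 0.326 with an estimated correlation. Relative to the mean of the 12 arrays, this list stood at 0.258 (replicate 1) and -0.00318 (replicate 2) on the unstimulated KD arrays. At 4 h it stood at -0.027 and 0.0243 in KD. A total of 2792 probe sets were called, 1480 higher and 1312 lower (1520 and 1533 with the stricter filter), and 1576 without KD LPS 4 h replicate 1, 1842 without KD LPS 4 h replicate 2 and 1326 without a trend in the variance prior.

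From 1 h to 4 h of LPS in KD, Fosb fell by 4.05 ± 0.63, Dusp5 by 3.65 ± 0.15 and Il10 by 3.15 ± 0.51, while Adamts4 rose by 4.35 ± 0.24 and Cd40 by 3.49 ± 0.16. Immediate early genes had 12 of 21 lower and 1 higher (13 and 1 adjusted over the list alone; median -1), and interferon-induced genes 16 of 37 higher and 2 lower (17 and 3; median 0.478). Stromal cell markers had 2 of 12 higher and 1 lower (2 and 1 adjusted over the list alone; median 0.18), with a camera adjusted p of 0.038 and an adjusted p = 0.429 with an estimated correlation. The cytokine list had 4 of 19 higher and 3 lower (4 and 3 adjusted over the list alone), and its camera adjusted p was 0.479. Its median (0.143) and mean (-0.0912) differed in sign. The comparison called 2354 probe sets, 1271 higher and 1083 lower. The count was 1489 without KD LPS 1 h replicate 1, 1301 without KD LPS 1 h replicate 2, 1218 without KD LPS 4 h replicate 1, 1438 without KD LPS 4 h replicate 2 and 960 without a trend in the variance prior.

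**Figure D2:**
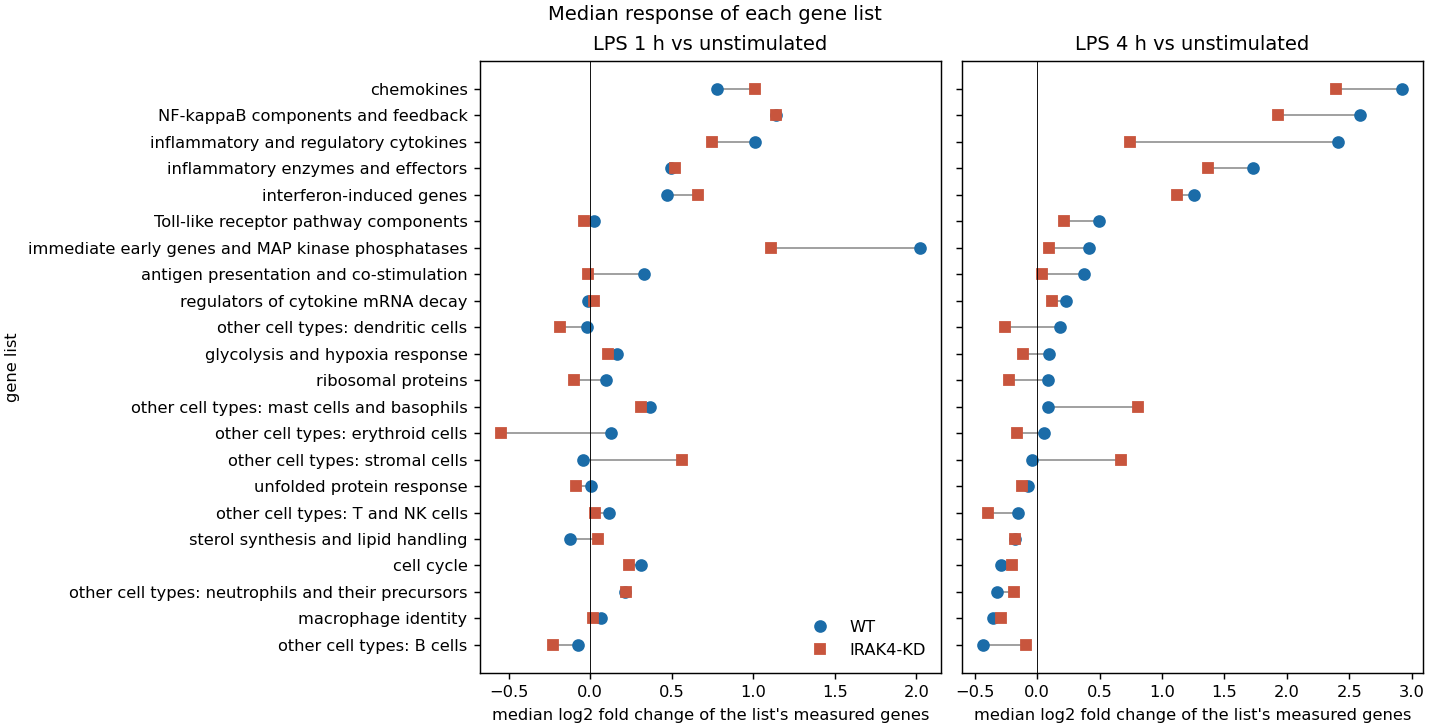
Median log2 fold change of the measured genes of each of the 22 gene lists after 1 h and 4 h of LPS, with circles for WT and squares for KD. At 4 h the cytokine list stood at 2.41 in WT and 0.746 in KD, and the interferon-induced list at 1.26 and 1.12.

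The test of the difference between the strains' responses addressed whether LPS acts differently when IRAK4 lacks kinase activity. At 4 h, the induction of several cytokine genes was smaller in KD. The log2 response of Il6 was lower by 4.79 ± 0.50 (adjusted p = 6.06e-05) and its signal at 4 h was 1751 ± 40.4 in WT and 97.3 ± 12.3 in KD (SD, n = 2). Unstimulated Il6 was at 0.9 and 0.6 on the WT arrays and 7.7 and 1.2 on the KD arrays, around or under the pseudocount, so the size of its interaction depends on that constant (-5.49 with a pseudocount of 1 and -4.08 with 23.4). For Il1b the interaction was -4.43 ± 0.26 (adjusted p = 3.01e-08), with 2744 ± 278 in WT and 370 ± 58.8 in KD at 4 h and a higher KD signal without LPS (36.2 ± 7.64 against 9.40 ± 1.98). Il1a (-3.72 ± 0.63, not called with a pseudocount of 1), U90926 (-3.32 ± 0.53), Trim36 (-2.68 ± 0.41), Nlrp3 (-2.62 ± 0.29) and Tnfsf9 (-2.48 ± 0.33) also had smaller responses in KD. Cish (-4.11 ± 0.99), Mefv (-2.85 ± 0.64) and Csf2 (-2.56 ± 0.53), the remaining genes of the 10 lowest, lost their calls in 6, 5 and 4 of the 12 fits with 1 array left out.

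Fos, an immediate early transcription factor gene, had the opposite difference (2.61 ± 0.17, adjusted p = 9.22e-08), since its signal at 4 h was 149 ± 19.2 in WT and 1441 ± 35.9 in KD. Jun, its partner in AP-1, differed the same way (1.07 ± 0.12). Of the 10 highest interactions, Gm11517 (3.26 ± 0.49) and Nrg2 (2.77 ± 0.47) were called in every fit with 1 array left out. The others were Nxn, AU041480, Top3a, Cxxc5, Slc2a8, Celsr3, Rai2 and Runx1t1, at 2.69 to 3.78, and each lost its call in 1 or more of those fits. Top3a, Cxxc5, Celsr3 and Rai2 were also among the lowest in KD against WT without LPS, as given below. A large part of their interactions thus lay in the unstimulated level.

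In the cytokine list, 7 of 19 genes had a smaller response in KD at 4 h and 0 a larger one (8 and 0 adjusted over the list alone), with a median difference of -1.79 and a camera adjusted p of 2.72e-12. Of 18 NF-κB genes, 5 were smaller (6 adjusted over the list alone, where 1 was larger; median -0.4), among them Rel (-1.64 ± 0.37, call lost in 6 of the 12 fits), Tnfaip3, which encodes a ubiquitin-editing enzyme (-1.22 ± 0.23), and Nfkbiz (-0.88 ± 0.16). Of 20 chemokines, 3 were smaller (8 adjusted over the list alone; median -0.563), including Ccl4 (-1.21 ± 0.19) and Ccl3 (-0.67 ± 0.11). Inflammatory enzymes and effectors had 6 smaller and 2 larger of 21 (7 and 3 adjusted over the list alone; median -0.254), with Serpinb2 at -2.22 ± 0.41 and Ptges at -1.61 ± 0.23. Toll-like receptor pathway components had 3 smaller of 26 (3 adjusted over the list alone; median -0.167), led by Peli1 (-1.13 ± 0.17). The calls of these 5 lists held with an estimated correlation. Interferon-induced genes had 4 smaller of 37 (6 adjusted over the list alone; median -0.205), among them Irf1 (-1.53 ± 0.23), Parp14 (-1.31 ± 0.15), Oasl1 (-1.03 ± 0.20, call lost in 2 of the 12 fits) and Ifih1, a sensor of double-stranded RNA (-0.95 ± 0.17). Their camera adjusted p was 7.27e-06, and the adjusted p = 0.128 with an estimated correlation. Mx1 and Ifit1, called in both strains, had interactions of -0.67 and -0.14 that were not called. Antigen presentation and co-stimulation had 3 smaller of 18 (7 adjusted over the list alone; median -0.395), among them Cd40 (-1.27 ± 0.22). The camera adjusted p was 0.00106, and the adjusted p = 0.142 with an estimated correlation. Immediate early genes had 3 smaller and 2 larger of 21 (7 and 2 adjusted over the list alone; median -0.405), including Csrnp1 (-2.40 ± 0.28). Camera gave an adjusted p of 0.0118, and the adjusted p = 0.158 with an estimated correlation. Ribosomal proteins had 3 smaller of 16 (9 adjusted over the list alone, where 1 was larger), with a median of -0.312, a camera adjusted p of 2.38e-05 and an adjusted p = 0.129 with an estimated correlation. The unstimulated KD arrays differed for this list, at 0.258 (replicate 1) and -0.00318 (replicate 2) relative to the mean of the 12 arrays.

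Stromal cell markers moved with the interaction at 4 h in the other direction. Of 12 such genes, 7 had a larger response in KD and 0 a smaller one (10 and 0 adjusted over the list alone), with a median of 0.924, Col6a1 at 1.49 ± 0.23 and a camera adjusted p of 1.12e-09 (adjusted p = 0.0471 with an estimated correlation). Dhcr7 had a smaller decrease in KD (1.47 ± 0.17) and Mki67 a smaller increase (-2.26 ± 0.34). Their lists were not called: sterol synthesis and lipid handling had 1 larger and 0 smaller of 21 (median 0.249, camera adjusted p = 0.429). The cell cycle list had 1 larger and 1 smaller of 27 (median 0.201, camera adjusted p = 0.621), so its median had the opposite sign to Mki67.

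The interaction at 4 h called 857 probe sets, 524 higher and 333 lower. Without a trend in the variance prior 11 were called (4 higher, 7 lower), and of the named genes Il6, Il1b, Fos, Csrnp1 and Trim36 kept their calls. The count was 285 without WT unstimulated replicate 1, 556 without WT unstimulated replicate 2, 274 without WT LPS 4 h replicate 1, 269 without KD LPS 4 h replicate 1 and 543 without KD LPS 4 h replicate 2. Of the 1940 probe sets that rose in WT, 257 had a smaller response in KD and 6 a larger one, against 23.1 and 36.4 if calls were independent. Selected in KD instead, 135 of 1480 that rose had a smaller response in KD and 193 a larger one, so the balance depends on the strain used for selection. Of 2842 that fell in WT, 350 had a positive interaction and 1 a negative one. The number of WT-induced probe sets with a smaller response was 114 without WT unstimulated replicate 1, 84 without WT LPS 4 h replicate 1, 96 without KD LPS 4 h replicate 1, 167 without KD LPS 4 h replicate 2 and 7 without a trend. The WT call and the interaction share the WT arrays, and the KD call and the interaction share the KD arrays. With a common response in both strains, 20 simulated sets gave a mean of 0.05 WT-induced probe sets with a smaller response and at most 1. Those sets held no true interaction, unlike the data with 857 called. They therefore cannot show how far the shared arrays shape these counts. Probe sets that rose in both strains at 4 h numbered 914, against 103 for independent lists, and 817 fell in both, against 133. The strains had separate control arrays.

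**Figure D3:**
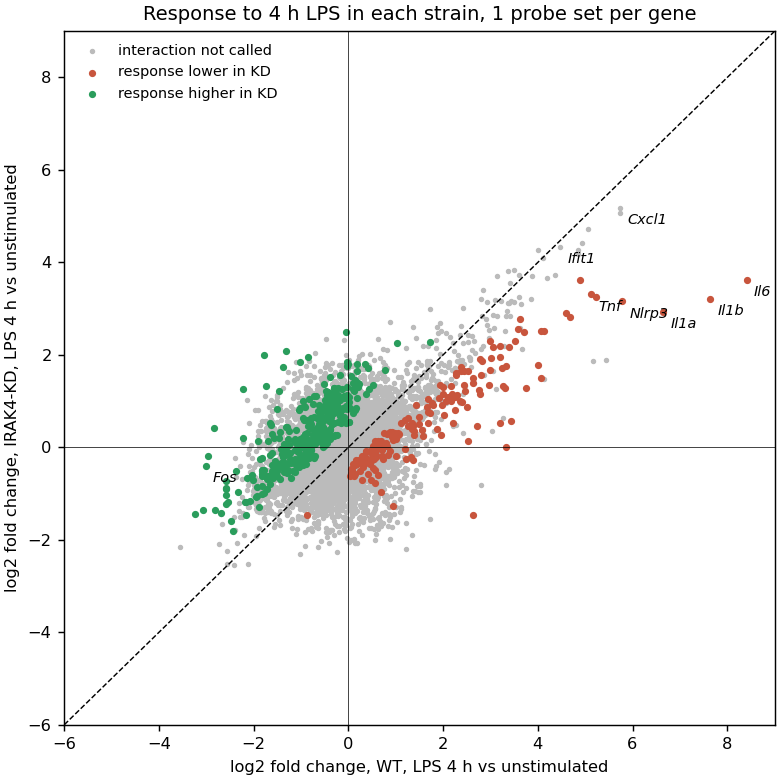
Log2 fold change after 4 h of LPS in WT (horizontal) against KD (vertical), 1 point per gene, with colours for a called interaction and a dashed line of equal response. Il6 lies at 8.41 in WT and 3.62 in KD, Il1b at 7.64 and 3.21, Ifit1 at 4.47 and 4.33, and Fos at -3.01 in WT. Unstimulated Il6 lay around or under the pseudocount, so the position of Il6 depends on that constant.

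At 1 h, the response of Il1b was smaller in KD by 2.68 ± 0.26 on the log2 scale (adjusted p = 6.54e-05), with 779 ± 111 in WT and 353 ± 27.0 in KD (SD, n = 2). KD against WT, Il1b differed by 1.55 ± 0.18 without LPS and by -1.13 ± 0.18 at 1 h, so more of this interaction lay in the unstimulated level than in the level under LPS. Cxcl5 differed by -2.51 ± 0.30 (adjusted p = 0.000773), Egr2 by -0.87 ± 0.13 and Tsn by -1.18 ± 0.14. Adam23 (1.78 ± 0.22), Gas1 (1.86 ± 0.24) and Tmem176b (1.52 ± 0.22) had a higher response in KD. These 7 were the named genes called in every fit with 1 array left out. The interaction of Tnf was -1.08 ± 0.20 (adjusted p = 0.0224) and that of Fos -0.95 ± 0.17 (adjusted p = 0.0199), with the call lost in 5 and 4 of those fits. Scarf1 (-3.88 ± 0.75), a scavenger receptor gene and the lowest value, lost its call in 8.

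Immediate early genes had 5 smaller responses of 21 in KD at 1 h and 0 larger (12 and 0 adjusted over the list alone), a median of -0.696 and a camera adjusted p of 7.41e-12, which held with an estimated correlation. KD against WT, the list's median was 0.366 without LPS and -0.395 at 1 h of LPS, so part of this interaction lay in the unstimulated level. Of 18 NF-κB genes, 2 were smaller (3 adjusted over the list alone; median -0.304). As a list, the camera adjusted p was 0.0015, and the adjusted p = 0.0664 with an estimated correlation. Cytokines had 2 smaller of 19 (2 adjusted over the list alone; median -0.264). Its camera adjusted p was 0.0112, and the adjusted p = 0.0743 with an estimated correlation. Chemokines had 2 smaller of 20 (6 adjusted over the list alone; median -0.101), with 0.0163 and an adjusted p = 0.0842 with an estimated correlation. Interferon-induced genes had 1 larger of 37 (4 adjusted over the list alone; median 0.173), Ifit2 (0.99 ± 0.19, call lost in 10 of the 12 fits). The camera adjusted p was 0.00954, and the adjusted p = 0.354 with an estimated correlation. Stromal cell markers had 1 larger of 12, Thbs2 (1.40 ± 0.25, call lost in 3 of the 12 fits; 6 larger adjusted over the list alone; median 0.451). Camera gave an adjusted p of 0.000436, and the adjusted p = 0.207 with an estimated correlation.

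The interaction at 1 h called 91 probe sets, 49 higher and 42 lower. Without a trend in the variance prior, limma called 0, with 2430 at an unadjusted p under 0.05 against 3041 with the trend. The count was 17 without WT unstimulated replicate 1 (7 higher, 10 lower), 15 without WT LPS 1 h replicate 2 (5 and 10), 15 without KD LPS 1 h replicate 1 (6 and 9), 56 without WT LPS 4 h replicate 1 (29 and 27), 56 without WT LPS 4 h replicate 2 (29 and 27), 60 without KD unstimulated replicate 2 (31 and 29) and 242 without KD unstimulated replicate 1 (175 and 67). It was 143 after quantile normalization (88 and 55). Of 806 probe sets that rose in WT at 1 h, 31 had a smaller response in KD and 5 a larger one, against 1.21 and 1.41 if calls were independent. In 20 simulated sets with a common response the mean number with a smaller response was 0.05 and the most was 1. As at 4 h, those sets held no true interaction, so they cannot show what the shared WT arrays add to the 31. Of 886 that rose in KD, 8 had a smaller response in KD and 32 a larger one. The number of WT-induced probe sets with a smaller response was 9 without WT unstimulated replicate 1, 10 without WT LPS 1 h replicate 2, 9 without KD LPS 1 h replicate 1, 48 without KD unstimulated replicate 1 and 0 without a trend.

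Without LPS, KD macrophages had lower levels of several inflammatory effector and stromal genes and higher levels of cell cycle genes. Lcn2, which encodes the iron-binding protein lipocalin-2, was at 675 ± 20.2 in WT and 144 ± 2.12 in KD (SD, n = 2), a log2 difference of -2.20 ± 0.13 (adjusted p = 5.67e-08). Grb14 (-2.30 ± 0.35), Postn, a matrix gene (-2.20 ± 0.29), Tmem176b (-2.15 ± 0.16), the matrix metalloproteinase gene Mmp14 (-2.08 ± 0.32) and Cfb, complement factor B (-2.06 ± 0.22), were also lower in KD. Mrc1, the mannose receptor gene, differed by -1.21 ± 0.14. Its list, macrophage identity, went the other way in its median (0.261), with 2 higher and 1 lower of 18 (5 and 1 adjusted over the list alone). Camera did not call that list (adjusted p = 0.0955). Cd5l (1.86 ± 0.32) and Nusap1, a mitotic spindle gene (1.81 ± 0.25), were higher, as were S100a8, a calcium-binding protein of myeloid cells (1.29 ± 0.12), and Itgax, which encodes CD11c (1.63 ± 0.25). These genes were called in every fit with 1 array left out. The highest difference, B130024G19Rik (2.87 ± 0.57), lost its call in 2 of them, Pspn (2.46 ± 0.59) in 3 and Chaf1b (2.20 ± 0.62) in 7. Cxxc5, Rai2, Celsr3 and Top3a, which differed by -2.29 to -2.24, lost theirs in 2 to 4.

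Of 21 inflammatory enzymes and effectors, 7 were lower and 1 higher in unstimulated KD cells (8 and 1 adjusted over the list alone), with a median of -0.195 and a camera adjusted p of 4.6e-05, and Saa3 at -1.44 ± 0.10. Of 27 cell cycle genes, 11 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.799, a camera adjusted p of 1.01e-10, Rrm2 at 1.74 ± 0.22 and Mki67 at 1.68 ± 0.24. Stromal cell markers moved with these groups, with 8 of 12 lower and 0 higher (11 and 0 adjusted over the list alone), a median of -0.723, a camera adjusted p of 6.05e-14, Col1a1 at -1.12 ± 0.14 and Col1a2 at -1.24 ± 0.19. The calls of these 3 lists held with an estimated correlation. Ribosomal proteins had 9 of 16 higher (12 adjusted over the list alone, median 0.334). Relative to the mean of the 12 arrays, they stood at 0.258 on KD unstimulated replicate 1, the array with the highest 3' to 5' ratios. On KD unstimulated replicate 2 they stood at -0.00318, and on the unstimulated WT arrays at -0.0911 and -0.0646. As a list, the camera adjusted p was 3.85e-07, and the adjusted p = 0.0789 with an estimated correlation. For its member Rps9 (0.46 ± 0.09, call lost in 1 of the 12 fits), another probe set was called in the opposite direction. Immediate early genes had 4 higher and 1 lower of 21 (7 and 2 adjusted over the list alone; median 0.366). Its camera adjusted p was 0.0491, and the adjusted p = 0.265 with an estimated correlation.

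This comparison called 1465 probe sets, 662 higher and 803 lower in KD, of which 107 and 226 differed at least 2-fold. The excess of lower calls turned without KD unstimulated replicate 2 (425 higher, 387 lower, 812 in all) and was larger without KD unstimulated replicate 1 (441 and 909). The count was 271 without WT unstimulated replicate 1, 831 without WT unstimulated replicate 2, 677 on the 4 arrays of the comparison alone and 69 without a trend in the variance prior. Of 72 called genes that the naming rule gave, 13 were called without a trend, among them Lcn2, Tmem176b, Cfb, Mrc1, Nusap1, S100a8 and Saa3, and also Grb14 and Mmp14, which lost their calls on the 4 arrays alone.

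**Figure D4:**
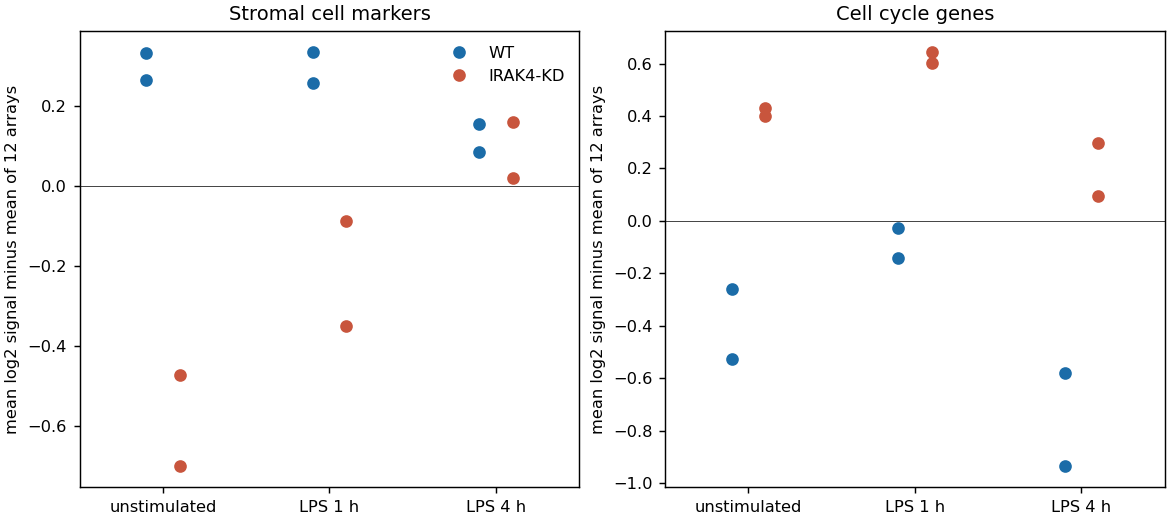
Mean log2 signal of the 12 stromal cell markers and the 27 cell cycle genes on each array, minus the mean of the 12 arrays, for WT and KD without LPS and after 1 h and 4 h of LPS. The median log2 difference of the stromal markers, KD against WT, was -0.723 without LPS and 0.0957 at 4 h, and that of the cell cycle genes was 0.799 and 1.02.

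After 1 h of LPS, the lowest values in KD relative to WT were Cxcl5 (-3.57 ± 0.21, adjusted p = 4.38e-08) and Slc36a2 (-2.55 ± 0.44). Postn (-2.09 ± 0.29), Cfb (-2.06 ± 0.22) and Lcn2 (-1.98 ± 0.13) were lower, as they were without LPS. Cxcl3 differed by -1.50 ± 0.16 and Tnfaip3 by -1.13 ± 0.16, whereas Nusap1 (2.5 ± 0.25), Urah (2.0 ± 0.25) and Gprasp1 (1.99 ± 0.24) were higher. Uty, Scarf1, Dcn, Il1a and U90926, which differed by -2.43 to -1.93, lost their calls in 3 to 6 of the 12 fits with 1 array left out, and Mtfr2 (2.84) and Nkain4 (2.57) lost theirs in 10 and 4. Lower members without higher ones were 4 of 21 immediate early genes (13 adjusted over the list alone), 5 of 18 NF-κB genes (9), 4 of 19 cytokines (4, where 1 was higher), 4 of 20 chemokines (6) and 7 of 21 inflammatory enzymes and effectors (10, where 2 were higher), with camera adjusted p of at most 0.000891. Cell cycle genes had 6 of 27 higher (15 adjusted over the list alone; median 0.723). Interferon-induced genes had 6 higher and 2 lower of 37 (12 and 2 adjusted over the list alone; median 0.337). The camera adjusted p was 4.64e-07, and the adjusted p = 0.0925 with an estimated correlation. Stromal cell markers had 5 lower and 1 higher of 12 (7 and 2 adjusted over the list alone; median -0.441). Camera gave an adjusted p of 7.63e-06, and the adjusted p = 0.118 with an estimated correlation. The comparison called 309 probe sets, 160 higher and 149 lower, and 152 without WT LPS 1 h replicate 2. Lower calls slightly outnumbered higher ones in 6 further fits, among them no filter (101 and 110) and the stricter filter (192 and 208). The share of lower calls was largest without KD LPS 1 h replicate 1 (42 higher, 87 lower, 129 in all), without KD LPS 1 h replicate 2 (44 and 81, 125 in all) and without a trend in the variance prior (3 and 14, 17 in all). Of 53 called genes that the naming rule gave, 7 were called without a trend, among them Cxcl5, Cfb, Lcn2, Nusap1 and Urah.

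After 4 h of LPS, Il6 (-4.11 ± 0.35), U90926 (-4.09 ± 0.37), Il1a (-3.98 ± 0.44), Il1b (-2.88 ± 0.18), Nlrp3 (-2.55 ± 0.20) and Tnfsf9 (-2.53 ± 0.24) were lower in KD than in WT. Fos (3.24 ± 0.12), Tifab (3.07 ± 0.23), Pbk, a mitotic kinase gene (2.99 ± 0.33), and Nap1l2 (2.91 ± 0.27) were higher. Shisa3 (-3.05) and Cish (-2.81) lost their calls in 3 of the 12 fits with 1 array left out. Lower members numbered 9 of 19 cytokines (12 adjusted over the list alone; median -1.42), 11 of 18 NF-κB genes (14; median -0.641), 11 of 21 inflammatory enzymes and effectors (14; median -0.741) and 8 of 20 chemokines with 1 higher (12 and 1; median -0.824), with camera adjusted p of at most 8.09e-13. Lcn2 was at -2.17 ± 0.13, Serpinb2 at -1.81 ± 0.29 and Ptges at -1.79 ± 0.16. Cell cycle genes had 13 of 27 higher (16 adjusted over the list alone, where 1 was lower; median 1.02), including Ccna2, which encodes cyclin A2 (2.86 ± 0.47), Bub1 (2.02 ± 0.43, call lost in 3 of the 12 fits) and Birc5 (1.73 ± 0.20). Interferon-induced genes had 6 lower and 1 higher of 37 (8 and 1 adjusted over the list alone; median -0.153). As a list, the camera adjusted p was 1.29e-05, and the adjusted p = 0.136 with an estimated correlation. Stromal cell markers had 2 higher and 1 lower of 12 (2 and 1 adjusted over the list alone), a median of 0.0957 and a camera adjusted p of 0.909. The comparison called 1500 probe sets, 873 higher and 627 lower. The excess of higher calls did not hold on the 4 arrays of the comparison alone (885 higher, 938 lower) and was 349 against 347 without KD LPS 4 h replicate 2. The count was 538 without WT LPS 4 h replicate 1, 899 without WT LPS 4 h replicate 2, 555 without KD LPS 4 h replicate 1, 696 without KD LPS 4 h replicate 2 and 504 without a trend in the variance prior. Of 62 called genes that the naming rule gave, 39 were called without a trend, and Ccna2, Bub1 and Cish were not.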

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

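Of the tests in this part, only those of the genes beside Irak4 and of the second stromal list were chosen before their results were seen; the tests of RNA quality, of stromal cells at 4 h, of the share of the response kept and of male animals were chosen afterwards.

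The results in this paragraph were picked out because a test of the difference between the strains' LPS responses was passed. At 1 h, 91 probe sets passed it, 17 without WT unstimulated replicate 1, 15 without WT LPS 1 h replicate 2, 15 without KD LPS 1 h replicate 1, 56 without WT LPS 4 h replicate 1, 56 without WT LPS 4 h replicate 2, 60 without KD unstimulated replicate 2 and 242 without KD unstimulated replicate 1. Among them, 4 genes were called in opposite directions in the strains: Smndc1 fell in WT (-0.50) and rose in KD (0.33), and Cnih4, Scarf1 and Uqcc2 did the reverse. These 4 genes, outside the naming rule in part, were chosen after their values were seen. The median interaction of the immediate early genes was -0.696, and this list alone kept its call at 1 h with an estimated correlation. Medians of lists whose call was lost with it were -0.304 for NF-κB genes, -0.264 for cytokines, -0.101 for chemokines, 0.173 for interferon-induced genes, -0.102 for Toll-like receptor pathway components, -0.268 for antigen presentation and co-stimulation, 0.451 for stromal cell markers and -0.148 for ribosomal proteins.

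At 4 h, 857 probe sets passed the test of the difference, 285 without WT unstimulated replicate 1, 556 without WT unstimulated replicate 2, 274 without WT LPS 4 h replicate 1, 269 without KD LPS 4 h replicate 1 and 543 without KD LPS 4 h replicate 2. Of 28 genes called in opposite directions in the strains, 24 fell in WT and rose in KD and 4 did the reverse. By size of interaction, the first of the 24 were Nxn (3.78, call lost in 1 or more fits with 1 array left out), Il7 (1.96) and Gas1 (1.87). Interactions can come from unstimulated levels as well as from levels under LPS, and these were not separated for the 28 genes. The 4 were H2-K1, Rhob, Sub1 and Uqcrh, with interactions of -0.68, -1.18, -0.78 and -0.64, and were chosen after their values were seen, except H2-K1. Lists that kept their calls with an estimated correlation had medians of -0.4 (NF-κB genes), -1.79 (cytokines), -0.563 (chemokines), -0.254 (inflammatory enzymes and effectors), -0.167 (Toll-like receptor pathway components) and 0.924 (stromal cell markers). Lists that lost them had medians of -0.405 (immediate early genes), -0.205 (interferon-induced genes), -0.395 (antigen presentation and co-stimulation) and -0.312 (ribosomal proteins).

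Stromal cell markers were lower in KD than in WT without LPS, with 8 of 12 called lower and a median log2 difference of -0.723, and 7 of 12 rose with LPS in KD at 4 h. RNA quality of KD unstimulated replicate 1, the array with the highest 3' to 5' ratios, is argued against as the whole cause: without that array the median was -0.83, and 12 of 12 genes had a difference below 0. That fit rests on KD unstimulated replicate 2, which stood apart on the fourth principal component (-65.28, the other arrays -27.87 to 25.22) and had the lower stromal level (-0.7 against -0.472), but without replicate 2 the median was -0.627. A smaller share of stromal cells in the unstimulated KD cultures predicted that a second list, sharing no member with the first, would be lower too. Its median was -0.675 (camera p = 2.81e-13, and 0.0175 with an estimated correlation). Of its 21 genes, 10 were called lower, and 14 rose with LPS in KD at 4 h. Shared regulation would lower both lists alike, so the second list cannot tell a smaller share from regulation. At 4 h of LPS the medians, KD against WT, were 0.0957 (first list) and 0.0743 (second list), so the lower level was not seen there. An effect of IRAK4 kinase activity on these genes within macrophages stays open and was not tested.

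The smaller cytokine induction in KD at 4 h was weighed against fewer stromal cells in the KD cultures at 4 h. The mean stromal difference minus 2 SE over 12 genes was -0.451, above the cytokine median of -1.42. Stromal marker RNA was thus not lower in KD by as much as the cytokines. It cannot settle the share of stromal cells, since 7 of the 12 markers rose with LPS in KD. The SE treats the 12 genes as independent, whereas their estimated correlation was 0.226. An LPS log2 response reduced by the same share in every induced gene is argued against, among genes of 2 lists that rose in WT. In KD, 13 cytokine genes kept 49.7% (SD 28.8, median 43%) of their WT log2 response and 29 interferon-induced genes 80.7% (SD 32.1, median 86.2%). The two-sided permutation p was 0.0045 in 100000 permutations across genes, which are not independent replicates. Such shares depend on the pseudocount and on unstimulated signals, which were near the pseudocount for Il6 and higher in KD for Il1b. The lists also differed in WT response (median log2 change 3.3 and 2.02), so the p-value does not isolate the kind of gene. The interferon-induced genes were not alone in keeping more than the cytokines. NF-κB genes kept 80% (median 82.2%), inflammatory enzymes and effectors 84.1% (median 73.9%) and chemokines 74.7% (median 85.1%). The differences of these 3 lists from the cytokines were not tested. An effect of IRAK4 kinase activity and other differences between the animals or cultures of the strains stay open and were not tested apart from each other.

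The 1465 probe sets called between the strains without LPS were weighed against 2 further differences between the animals. A chromosome segment around Irak4 from another mouse strain predicted more calls among its neighbours, which were not seen. Among the 200 tested neighbours of Irak4, 5 (2.5%) were called against 823 of 12653 other genes (6.5%). The odds ratio was 0.369 (95% interval 0.118 to 0.879, one-sided Fisher's exact p = 0.997 for more calls). Called neighbours were Fbln1 and Pfdn5, higher in KD, and Pus7l, Scaf11 and Zfp740, lower in KD. These counts argue against a segment with more calls across that window. They cannot decide on a segment of a few genes, and 200 genes were too few to hold most calls. A smaller share of male animals behind the KD cultures cannot be told apart from other sources. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in KD, with log2 differences of -1.49, -1.52 and -1.79 over the 3 conditions. Xist, which that explanation needs to be higher, differed by -0.125 (SE 0.0823). Mean Xist signal was 1464 in WT and 1344 in KD, and Eif2s3y was at 829 ± 44.3 and 294 ± 27.5 (SD, n = 6 arrays). Both genes thus had signal in both strains, and Eif2s3y varied little within a strain. Whether the arrays of a strain shared animals is not given by the labels. If they did, the p-values between strains carry no spread between animals. The kinase-dead change itself stays among the open explanations, as untested apart from these differences between the animals.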

How the results depend on the processing

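The replacement of the interaction by KD against WT under LPS was chosen after the data were seen; the other alternatives were planned. Direction was compared only where the main fit or the alternative called the named gene or list test. Of these, 0 reversed under the alternatives chosen before the data were examined. The added one was run on 2 counts alone. Where values moved, the cause was not tested unless stated.

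Without a trend in the variance prior, the counts of called probe sets in WT were 487 (1 h), 3150 (4 h) and 2732 (4 h against 1 h), in KD 506, 1326 and 960, and between the strains 69 (unstimulated), 17 (LPS 1 h) and 504 (LPS 4 h). The interactions had 0 (limma; 2430 at an unadjusted p under 0.05) at 1 h and 11 at 4 h, and WT-induced probe sets with a smaller response in KD numbered 0 and 7. With a minimum absolute log2 change of 1, which by construction removes smaller changes, the counts in the same order were 548, 1904, 1636, 564, 979, 794, 333, 117, 540, 47 and 440, with 11 and 107 smaller responses. On the arrays of the comparison alone, KD at 1 h had 805, KD against WT unstimulated 677 and the interaction at 1 h 39, with 13 smaller responses. The interaction at 1 h had 143 after quantile normalization, 52 with no filter and 156 with the stricter filter, which also gave 51 smaller responses. KD against WT under LPS in place of the interaction gave 77 at 1 h and 531 at 4 h. Of the 242 list tests, 99 were called with the preset and 59 with an estimated correlation.

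With 1 array left out, which leaves a group with 1 array, counts ranged from 739 to 1932 (WT 1 h), 2899 to 5058 (WT 4 h), 2740 to 4724 (WT 4 h against 1 h), 818 to 1567 (KD 1 h), 1576 to 2873 (KD 4 h), 1218 to 2633 (KD 4 h against 1 h), 271 to 1523 (KD against WT unstimulated), 125 to 429 (LPS 1 h), 538 to 1696 (LPS 4 h), 15 to 242 (interaction 1 h) and 269 to 923 (interaction 4 h). Smaller responses in KD ranged from 9 to 48 at 1 h and from 84 to 285 at 4 h, and called list tests from 95 to 101. The lowest counts came without WT unstimulated replicate 1 (739, 271 and 9), WT LPS 4 h replicate 1 (2899, 2740, 538 and 84), KD LPS 1 h replicate 1 (818), KD LPS 4 h replicate 1 (1576, 1218 and 269), KD LPS 1 h replicate 2 (125 and 95) and WT LPS 1 h replicate 2 (15).

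With the replicate number as a block, 1709 became 1631 (WT 1 h), 4782 became 4649 (WT 4 h), 857 became 767 and 91 became 119. Correlations between replicate differences over 15 pairs of groups were -0.0682 to 0.0401, so no effect shared by a replicate number was seen and the block was not used elsewhere. This cannot show whether cultures with the same number shared an animal or a preparation, which the labels do not say.

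For 750 results of named genes, called or not, the side of the threshold was compared, and direction only where a fit called the result. Of these, 710 were unchanged after quantile normalization, 675 with no filter, 716 with a pseudocount of 1 and 741 with one of 23.4. Without a trend 429 were unchanged, on the arrays of the comparison alone 647, with the block 726 and with the minimum change 554. The stricter filter tested 658 of them and 656 were unchanged. It gave no value for the other genes, and for 209 of the 242 list tests alone it gave one. Arrays carry no read depth, and between 17.06% and 22.91% of an array's values lay under the pseudocount of 4.4.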

Other observations

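Cell cycle genes were higher in KD in all 3 conditions, with medians of 0.799 without LPS, 0.723 at 1 h and 1.02 at 4 h. Neither the cause of this difference nor that of the ribosomal protein difference was tested. No further hypothesis was tested.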
